A study of Homo sapiens with 8 samples.

How the data were processed

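RNA sequencing was compared between 8 libraries of MDA-MB-231 cells in 4 groups of 2: control and ETV1, ETV4 and ETV5 knockout cells, each as monolayers on plastic and in collagen I gels. Per the labels, guide RNAs and Cas9 were brought in by nucleofection, and the knockout label names all 3 genes. The label of the control monolayers names a control guide alone, while that of the control gels names Cas9 with a control guide. Whether the control monolayers also received Cas9 is not given in the sources used here. Per the labels, cells grew in DMEM/F12 with serum, gels were digested with collagenase I at 37 °C, pipetted, washed and frozen as pellets, monolayers were lysed directly, RNA was treated with DNase, and libraries were made with a stranded poly(A) mRNA kit. The labels give alternative collagen I concentrations for the gels, without saying which sample had which. The time in culture, and whether the 2 libraries of a group came from separate cultures, are not given in the sources used here. The p values therefore measure only the spread between these libraries.

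The deposited table holds raw counts per gene symbol, in a column per library. Per the submitters' processing notes, reads were checked with FastQC 0.11.9, aligned with STAR 2.7.9a to hg38 and counted with featureCounts, with R 4.1.1. The featureCounts version, the annotation and the strand setting are not given in the sources used here. Counts of paralogs with near-identical sequence and of genes that overlap on opposite strands are therefore uncertain. Library totals ran from 15824504 to 23896899 counts, mitochondrially encoded genes took 2.65 to 4.47% of them, and the edgeR common dispersion was 0.00163, a biological coefficient of variation of 4.03%. The replicate libraries varied more than counting error alone, with a chi-squared per degree of freedom of 2.54 to 6.31. Whether the numbers 1 and 2 pair libraries across groups is not given in the sources used here, and the main model pairs none. Across genes, the replicate differences of any 2 groups had correlations of -0.063 to 0.082.

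Of 61228 genes in the table, 15568 passed edgeR's filterByExpr (minimum count 10) and held 99.89% of the counts. Counts were scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3, in a model of group means over all 8 libraries. The test was the quasi-likelihood F-test, robust, with 4 residual degrees of freedom. It also draws on the spread of the other genes. For ETV1, ETV4 and ETV5 it had 34.3 degrees of freedom in all, so their p values rest largely on spread shared across genes. The 5 contrasts were knockout against control in monolayers and in gels, gels against monolayers in control and in knockout cells, and the interaction (the knockout effect in gels minus that in monolayers). P values are two-sided and adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05, and each list's members were also adjusted over the list alone. CPM values use the TMM factors, and the SE of a log2 fold change comes from the fit.

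The groups, comparisons, gene lists, tests, alternatives and the rule for naming genes were written before the data were examined. The rule named ETV1, ETV4 and ETV5 everywhere. In each pairwise comparison it took the 5 largest rises and 5 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 CPM, a symbol that is not a clone or LOC identifier, and group values that did not overlap. From each list it took up to 3 members with the smallest adjusted p, or 2 where fewer than 3 passed. For the interaction it took the 5 genes of each sign with the smallest adjusted p.

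The 33 lists covered the targeted genes, ERK pathway output, other ETS factors, matrix proteases and inhibitors, collagens, matrix glycoproteins and crosslinkers, integrins and collagen receptors, the mesenchymal and epithelial states, mammary luminal and basal markers, S phase, G2/M, hypoxia response, glycolysis, cholesterol synthesis, interferon-stimulated genes, NF-kB targets and cytokines, p53 targets, the integrated stress response and amino acids, the unfolded protein response, YAP/TAZ targets, SRF and actin genes, TGF-beta targets, the immediate-early and dissociation response, heat shock and oxidative phosphorylation. Mitochondrially encoded genes, cytoplasmic ribosomal proteins and replication-dependent histones served as signs of RNA quality, and leukocyte, endothelial, fibroblast and luminal breast line markers stood for other cell types. Of these, 32 had at least 3 tested members. The fibroblast list had 2 tested members of 14 and was not tested. Some lists share genes, such as hypoxia response and glycolysis with 5. Lists were tested with camera of limma 3.58.1 (preset correlation 0.01, prior count 2), which asks whether a list's genes move one way compared with the other genes, and again with a correlation estimated from the data. With the estimate, 4, 6, 5, 4 and 7 of 32 lists had an unadjusted p under 0.05 in the 5 contrasts in the order above, and the lowest adjusted p values were 0.116, 0.147, 0.0923, 0.118 and 0.111. The fry test was run beside it. Its directional p asks whether a list's genes move on balance one way, its mixed p whether they change in either direction, and neither compares the list with other genes. A range of a list's adjusted p is over the alternatives with the preset correlation, without fry and the estimated correlation.

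The alternatives were DESeq2 size factors, upper-quartile factors and library size alone in edgeR, the DESeq2 1.42.0 Wald test, limma-voom, no filter, at least 1 CPM in 4 libraries, a replicate block, only the 2 groups compared, a prior count of 0.5, edgeR's test against a fold of 1.5, and leaving out each library in turn, when the lone library of a group was assumed to vary like the others. A correction per library for transcript length and GC content (15178 genes with an annotated transcript, 97.49% of those tested, fitted on 10832) was chosen after seeing the data. The test was checked on simulated counts with 200 changed genes in 1 draw per contrast and kind of dispersion: 69.7 to 90.8% of genes changed by 2-fold were recovered, 4.96 to 15.4% of calls were false, and 4.72 to 5.12% of unchanged genes had a p under 0.05. The share recovered at 1.5-fold was 46.2% for the interaction and 70.1% for knockout in monolayers with dispersions per gene, and 63.1% and 72.7% with trend dispersions. Fewer genes changed in the simulations than were called in the data, and the adjusted threshold depends on that number. The simulated shares may therefore not carry over to the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.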

Results

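Messenger RNA was sequenced in MDA-MB-231, a human triple-negative breast cancer line derived from a metastasis. The cells had received control guide RNAs, or the Cas9 nuclease with guides against ETV1, ETV4 and ETV5, the 3 transcription factors of the PEA3 group of the ETS family. Of the control groups, only the gels have a label that names Cas9. If the control monolayers received none, the knockout effect in monolayers, the change from monolayers to gels in control cells and the interaction also hold an effect of Cas9, which the knockout effect in gels does not. Each kind of cell was grown as a monolayer on plastic (2D) or in a gel of collagen I (3D), which gave 4 groups of 2 libraries. The control monolayers held 23896899 and 15824504 counts, the knockout monolayers 16204101 and 17957151, the control gels 21399230 and 18806653, and the knockout gels 18740354 and 19250921. Levels are given in CPM, counts scaled to a common library size, as the mean and SD of the 2 libraries of a group, and changes as log2 fold changes with the SE from the edgeR fit. Of 15568 genes tested, the first principal component (44.7% of the variance) separated gels from monolayers, and the second (22.6%) separated knockout from control libraries.

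The targeted genes themselves showed how far their transcripts were reduced in the knockout cells. ETV1 transcripts fell in both cultures, from 202 ± 3.2 to 143 ± 11.2 CPM in monolayers and from 219 ± 3.26 to 139 ± 2.12 CPM in gels (SD, n = 2). These are changes of -29% (log2 -0.50 ± 0.051 SE, adjusted p = 3.75e-09) and -36.5% (log2 -0.66 ± 0.051, adjusted p = 3.1e-12). ETV4 changed by -26.7% in monolayers, from 85.2 ± 5.58 to 62.3 ± 1.62 CPM (adjusted p = 9.94e-07), and by -32.8% in gels, from 96.7 ± 0.129 to 65 ± 2.89 CPM (adjusted p = 3.61e-09). ETV5 did not change detectably: its log2 differences were 0.04 in monolayers (95% interval -0.08 to 0.14, adjusted p = 0.718) and 0.02 in gels (-0.09 to 0.13, adjusted p = 0.808), at 115 ± 4.09 CPM in control monolayers. On GRCh38, ETV1 lies on chromosome 7 (13891228 to 13991425), ETV4 on chromosome 17 (43527844 to 43579620) and ETV5 on chromosome 3 (186046308 to 186110318), all on the minus strand. An edit that ends the reading frame can leave the transcript in place, and gene counts show neither the edits nor the proteins.

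**Figure D1:**
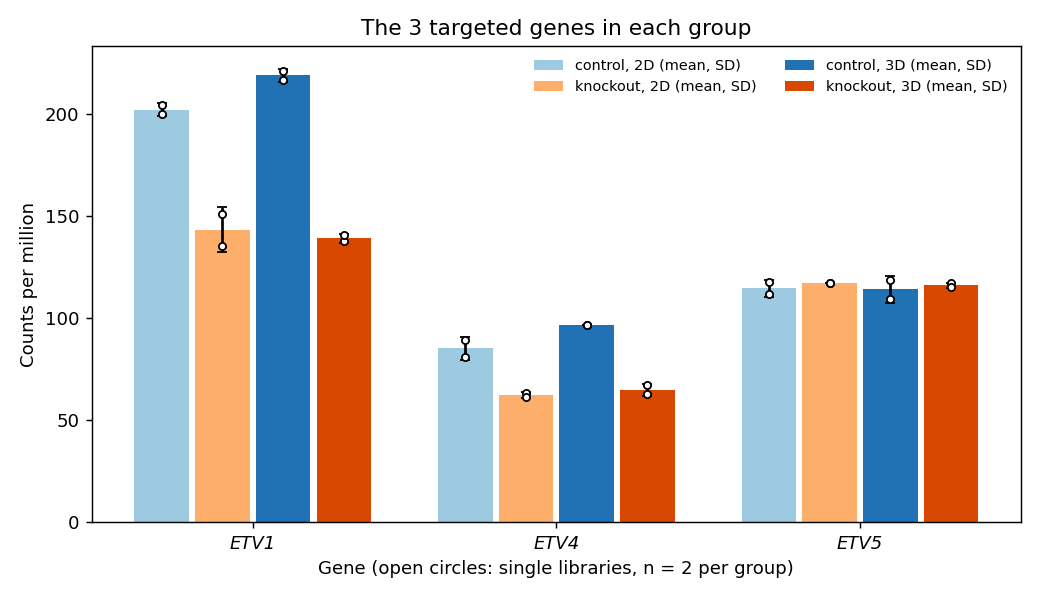
CPM of ETV1, ETV4 and ETV5 in the 4 groups, as bars for the group mean with the SD and open circles for the 2 libraries. ETV1 and ETV4 were lower in all knockout libraries than in all control libraries, and ETV5 lay between 110 and 119 CPM in all 8.

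The comparison of knockout with control monolayers asks which genes changed with the knockout in cells on plastic. In the knockout monolayers 14 of 23 tested NF-kB targets and cytokines and 15 of 37 interferon-stimulated genes rose, and 18 of 25 genes of cholesterol synthesis fell. With an estimated correlation these lists had adjusted p = 0.116, 0.332 and 0.274, so their calls as lists were lost. The gene of the cytokine interleukin-1 beta, IL1B, rose from 3.25 ± 0.322 to 14.9 ± 1.92 CPM (log2 2.22 ± 0.17, adjusted p = 1.75e-12), and the interferon-induced OASL from 5.84 ± 1.04 to 24.4 ± 1.65 CPM (log2 2.09 ± 0.13, adjusted p = 1.25e-14). Of 5 genes with the largest falls, CST4 and CST1 encode secreted inhibitors of cysteine proteases. CST4 went from 73.6 ± 2.33 to 16 ± 2.29 CPM and CST1 from 121 ± 8.34 to 37 ± 0.613 CPM (adjusted p = 3.04e-20 and 1.08e-18). Among the largest rises were also AKR1C1, CEMIP and RNF128 (log2 1.87, 1.86 and 1.86), and the other large falls were in INHBB, TFF2 and CD22 (log2 -1.90, -1.73 and -1.67).

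Of 23 tested NF-kB targets and cytokines, 14 rose in the knockout monolayers (16 adjusted over the list alone), among them CXCL8, a chemokine for neutrophils, from 8.35 ± 0.935 to 27.3 ± 2.89 CPM, and PTGS2, a prostaglandin synthase, by 1.58 on the log2 scale. The median log2 change of the list was 0.27 (camera adjusted p = 4.04e-09, and adjusted p = 0.116 with an estimated correlation). Of 37 interferon-stimulated genes, 15 rose (15 adjusted over the list alone), IFIT1 by 1.00 and IFIT2 by 0.88. The median was 0.23 (adjusted p = 6.52e-05, and adjusted p = 0.332 with an estimated correlation). Of 20 TGF-beta targets, 11 rose and 1 fell (11 and 1 adjusted over the list alone). Their median was 0.30 (adjusted p = 7.23e-05, and adjusted p = 0.274 with an estimated correlation). PMEPA1, a feedback gene of that pathway, went from 37.7 ± 2.86 to 108 ± 2.76 CPM and TGFBI, a matrix protein that TGF-beta induces, rose by 1.56 ± 0.089 on the log2 scale. Of 43 genes of S phase and DNA replication, 13 rose (13 adjusted over the list alone, with 2 lower), such as RRM2 (log2 0.45). Their median was 0.08 (adjusted p = 0.00242, and adjusted p = 0.332 with an estimated correlation).

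Of 25 genes of cholesterol synthesis and uptake, 18 fell (18 adjusted over the list alone) and 7 did not pass. The median was -0.35 (adjusted p = 2.92e-10, and adjusted p = 0.274 with an estimated correlation). HMGCS1, an early enzyme of the pathway, went from 110 ± 2.59 to 70 ± 3.11 CPM. Of 30 genes of the integrated stress response and amino acid supply, 17 fell, such as the serine synthesis gene PSAT1 (log2 -0.44), and 3 rose (18 and 5 adjusted over the list alone). The median was -0.24 (adjusted p = 0.000118, and adjusted p = 0.569 with an estimated correlation). Of 24 YAP/TAZ targets, 9 fell and 2 rose (10 and 2 adjusted over the list alone), with CCN2 going from 557 ± 7.99 to 320 ± 6.47 CPM. Their median was -0.10 (adjusted p = 0.00897, and adjusted p = 0.332 with an estimated correlation). Of 35 hypoxia-response genes, 15 fell, such as the carbonic anhydrase gene CA9 (log2 -0.85), and 2 rose, VEGFA by 0.56 on the log2 scale (17 and 5 adjusted over the list alone). Their median was -0.16 (adjusted p = 0.00542, and adjusted p = 0.718 with an estimated correlation).

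Genes of adhesion and matrix moved both ways in the knockout monolayers. The beta 4 integrin gene ITGB4, whose product binds laminin, fell from 346 ± 23.3 to 149 ± 4.64 CPM, and COL13A1, a transmembrane collagen, from 491 ± 28.2 to 244 ± 2.67 CPM, while TIMP1, an inhibitor of metalloproteinases, rose from 172 ± 2.87 to 283 ± 8.34 CPM. Of 23 matrix proteases and inhibitors, 9 rose and 4 fell (11 and 4 adjusted over the list alone). The median was 0.13 (adjusted p = 0.0348, and adjusted p = 0.419 with an estimated correlation). Genes that report ERK signalling also split: 9 of 22 fell, among them the feedback phosphatases DUSP5 (log2 -0.76) and DUSP6 (log2 -0.58) and the inhibitor SPRY1 (log2 -0.70), and 5 rose (9 and 6 adjusted over the list alone), with a median of 0.06, a mean of -0.05 and an adjusted p of 0.787. Of 39 oxidative phosphorylation genes, 5 rose (3 adjusted over the list alone). Their median was 0.07 (adjusted p = 0.0161, and adjusted p = 0.679 with an estimated correlation). Of 16 replication-dependent histone genes, whose transcripts lack a poly(A) tail and so report RNA selection as well as S phase, 4 rose (6 adjusted over the list alone). Their median was 0.69 (adjusted p = 4.85e-05, and adjusted p = 0.127 with an estimated correlation).

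The other lists did not pass in this comparison. Their camera adjusted p values were 0.473 for collagens (8 higher and 4 lower of 21), 0.898 for matrix glycoproteins and crosslinkers, 0.787 for integrins and collagen receptors, 0.911 for the mesenchymal and 0.933 for the epithelial state, 0.787 for mammary luminal and basal markers, 0.311 for other ETS factors, 0.959 for G2/M and mitosis, 0.787 for glycolysis, and 0.991 for p53 targets. They were 0.236 for the unfolded protein response, 0.0647 for SRF and actin genes, 0.968 for immediate-early genes, 0.137 for heat shock, 0.206 for mitochondrially encoded genes, 0.643 for cytoplasmic ribosomal proteins, and 0.0632 for the 3 targeted genes as a list. Of these, SRF and actin genes, ribosomal proteins and the targeted genes did pass in some alternative with the preset correlation. Median, mean and camera direction differed in sign for 8 lists, all without a call: ERK output, matrix glycoproteins, the mesenchymal and epithelial states, G2/M, glycolysis, immediate-early genes and luminal markers.

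In all, 2989 of 15568 genes changed between knockout and control monolayers, 1494 higher and 1495 lower, with a median size of 0.32 (log2) among them, and 126 changed by more than 1.5-fold by edgeR's test against that fold. The number of changed genes dropped to 1864 without control library 1, 1872 without knockout library 1 and 1978 without knockout library 2, and 1742 passed by DESeq2. The call on matrix proteases was lost without control library 1 (adjusted p = 0.116) and knockout library 2 (0.0647), that on hypoxia genes without control library 2 (0.115), and that on oxidative phosphorylation without control library 1 (0.254), knockout library 1 (0.0655) and knockout library 2 (0.0553) and after correction for length and GC content (0.176), over ranges of 0.0272 to 0.116, 2.99e-05 to 0.115 and 0.00524 to 0.254 in all alternatives with the preset correlation. The fold changes in monolayers also followed transcript length, with a Spearman rho of -0.312 across 10415 protein-coding genes (genes are not independent replicates), and GC content, with a rho of 0.198.

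The comparison of knockout with control gels asks the same question in collagen. In the knockout gels 30 of 35 hypoxia-response, 15 of 18 glycolysis and 22 of 25 cholesterol genes fell, while 29 of 43 S phase and 25 of 38 G2/M genes rose. With an estimated correlation these lists had adjusted p = 0.257, 0.329, 0.147, 0.147 and 0.147, so their calls as lists were lost. CA9 fell from 43.1 ± 3.55 to 3.61 ± 0.0748 CPM (log2 -3.58 ± 0.13, adjusted p = 3.8e-17) and NDRG1, another gene induced by low oxygen, from 582 ± 30.4 to 95.7 ± 0.000294 CPM (log2 -2.61 ± 0.079, adjusted p = 9.94e-11). CST1 went from 73.9 ± 8.1 to 6.07 ± 0.0926 CPM, CST4 from 50.7 ± 2.73 to 5.5 ± 0.0422 CPM and PPFIA4 from 30.4 ± 0.727 to 2.44 ± 1.2 CPM, the other large falls. CYP1B1, a monooxygenase, rose from 10.3 ± 0.482 to 39.4 ± 0.602 CPM (log2 1.94 ± 0.096, adjusted p = 1.91e-17), and OASL, CEMIP, CRISPLD2 and AQP3 rose by 1.88, 1.67, 1.61 and 1.36 on the log2 scale.

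Of 35 hypoxia-response genes, 30 fell in the knockout gels and 1 rose (30 and 1 adjusted over the list alone). The median was -0.58 (adjusted p = 3.13e-17, and adjusted p = 0.257 with an estimated correlation). BNIP3, a mitophagy gene, went from 461 ± 9.89 to 167 ± 5.27 CPM. Of 18 glycolysis genes, 5 of which are also in the hypoxia list, 15 fell (15 adjusted over the list alone), with PGK1 going from 1490 ± 71.6 to 797 ± 28.5 CPM, LDHA changing by -0.62 and ENO2 by -1.11 on the log2 scale. The median was -0.37 (adjusted p = 6.43e-09, and adjusted p = 0.329 with an estimated correlation). Of 25 cholesterol genes, 22 fell (24 adjusted over the list alone), with HMGCS1 going from 163 ± 3.12 to 69 ± 0.8 CPM. Their median was -0.63 (adjusted p = 1.11e-16, and adjusted p = 0.147 with an estimated correlation). The same 18 cholesterol genes that fell in monolayers fell in gels, and 15 hypoxia-response genes fell in both cultures.

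**Figure D2:**
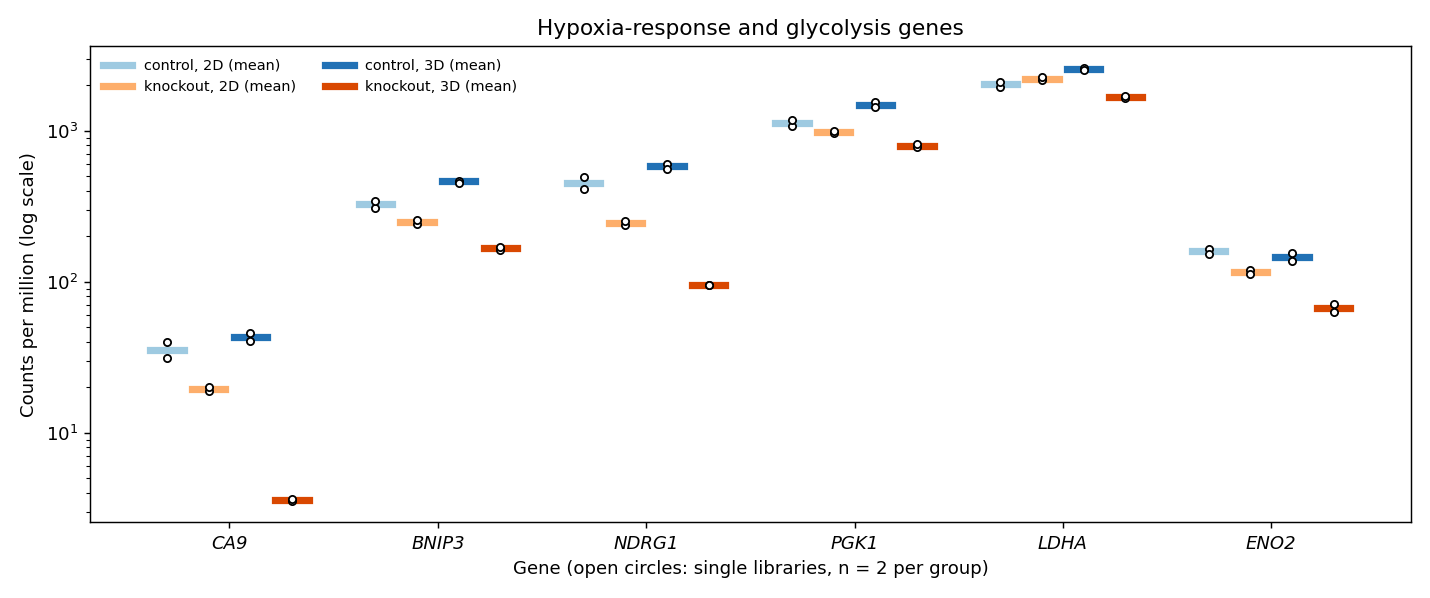
CPM (log scale) of 6 hypoxia-response and glycolysis genes in the 4 groups, with a line for the group mean and open circles for the 2 libraries. For each of the 6 genes the knockout gels were lowest, with CA9 at 3.61 CPM against 19.5 to 43.1 CPM in the other groups.

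Of 43 S phase genes, 29 rose in the knockout gels (33 adjusted over the list alone), RRM2 from 277 ± 3.3 to 407 ± 15.1 CPM. The median was 0.18 (adjusted p = 1.02e-10, and adjusted p = 0.147 with an estimated correlation). Of 38 genes of G2/M and mitosis, 25 rose (29 adjusted over the list alone), with the proliferation marker MKI67 going from 472 ± 20.3 to 603 ± 10.4 CPM. The median was 0.16 (adjusted p = 4.23e-08, and adjusted p = 0.147 with an estimated correlation). Of 37 interferon-stimulated genes, 13 rose and 2 fell (13 and 4 adjusted over the list alone), ISG15 by 1.04 and IFIT1 by 1.08. The median was 0.10 (adjusted p = 0.0114, and adjusted p = 0.443 with an estimated correlation). The 12 interferon-stimulated genes that rose in both cultures included OASL and IFIT1. Of 39 oxidative phosphorylation genes, 10 rose (10 adjusted over the list alone), CYC1 by 0.24. Their median was 0.11 (adjusted p = 0.000281, and adjusted p = 0.443 with an estimated correlation).

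Of 20 integrins and collagen receptors, 8 fell, 4 rose and 8 did not pass in the knockout gels (9 and 4 adjusted over the list alone), ITGB4 going from 533 ± 32.6 to 166 ± 1.71 CPM. Their median was -0.16 (adjusted p = 0.0288, and adjusted p = 0.257 with an estimated correlation), and the call was also lost without knockout library 1 (0.0613, range 0.0203 to 0.0613 over the alternatives with the preset correlation). PLAT, the tissue plasminogen activator gene, went from 390 ± 8.18 to 146 ± 1.73 CPM, PLAU, the urokinase gene, from 439 ± 3.26 to 301 ± 5.38 CPM, and LOX, which crosslinks collagen, from 91.1 ± 5.69 to 38.8 ± 0.653 CPM. COL13A1 went from 533 ± 2.09 to 232 ± 0.921 CPM, whereas THBS1, a matrix glycoprotein, rose from 413 ± 9.36 to 862 ± 23.3 CPM. As lists, matrix proteases (3 higher and 7 lower of 23, adjusted p = 0.342), collagens (1 higher and 8 lower of 21, adjusted p = 0.0701) and matrix glycoproteins (6 higher and 11 lower of 27, adjusted p = 0.0775) did not pass. Of these, collagens did pass in some alternative with the preset correlation. Of 22 ERK output genes, 9 fell, such as DUSP6 (log2 -0.57) and DUSP4 (log2 -0.43), and 5 rose (adjusted p = 0.342 for the list), and 7 fell in both cultures.

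Of the 3 lists that report RNA quality, ribosomal proteins and histones passed in this comparison. Of 45 cytoplasmic ribosomal protein genes, 16 were higher in the knockout gels (18 adjusted over the list alone). The median was 0.09 (adjusted p = 5.7e-05, and adjusted p = 0.597 with an estimated correlation). Of 16 histone genes 6 were higher (7 adjusted over the list alone). The median was 0.63 (adjusted p = 0.000152, and adjusted p = 0.147 with an estimated correlation). Mitochondrially encoded genes did not pass (median -0.22, adjusted p = 0.274), but did without control library 1 (0.00365) and knockout library 1 (0.00418), in a range of 0.00365 to 0.623. NF-kB targets (4 higher and 5 lower of 23, adjusted p = 0.823), TGF-beta targets (6 higher and 3 lower of 20, adjusted p = 0.0775) and the stress and amino acid list (7 higher and 7 lower of 30, adjusted p = 0.816) did not pass in gels. Of these, TGF-beta targets did pass in some alternative with the preset correlation. Median, mean and camera direction differed in sign for 5 lists without a call: matrix proteases, the mesenchymal state, NF-kB targets, the stress and amino acid list and leukocyte markers.

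In all, 3721 genes changed between knockout and control gels, 1786 higher and 1935 lower. By edgeR's test against a fold of 1.5, 164 changed by more than that fold, of which 132 were lower. The majority turned with DESeq2 size factors (1969 higher and 1845 lower), with library size alone (1878 and 1868) and after correction for length and GC content (2395 and 1897), and was 1519 and 2050 with upper-quartile factors. The number of changed genes dropped to 2095 without control library 1, 2158 without control library 2 and 2383 without knockout library 2, and 2352 passed by DESeq2. Across genes the fold changes had a rho of -0.114 with transcript length and -0.124 with GC content.

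The comparison of control gels with control monolayers asks what culture in collagen changed in cells without the knockout. Immediate-early genes, which respond within minutes to growth factors and to handling, showed the largest rises. FOS rose from 7.77 ± 0.11 to 697 ± 13.9 CPM (89.4-fold, log2 6.48 ± 0.066, adjusted p = 1.81e-39), FOSB from 3.64 ± 0.319 to 308 ± 29.3 CPM, NR4A1 from 3.76 ± 0.144 to 66.2 ± 4.39 CPM and ATF3 from 9.12 ± 0.257 to 125 ± 8.75 CPM. Of 24 members of the list of immediate-early and dissociation genes, 20 rose (21 adjusted over the list alone). Their median was 0.64 (adjusted p = 3.74e-16, and adjusted p = 0.0923 with an estimated correlation). Per the labels, gels were digested with collagenase at 37 °C and pipetted before the cells were pelleted, while monolayers went directly into RNA extraction, so culture and harvest differed together, as did the mention of Cas9 in the control labels. Heat shock genes, which also report handling, did not pass as a list (4 higher and 3 lower of 14, adjusted p = 0.784; 1 higher and 4 lower with library size alone, 2 and 3 with upper-quartile factors).

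**Figure D3:**
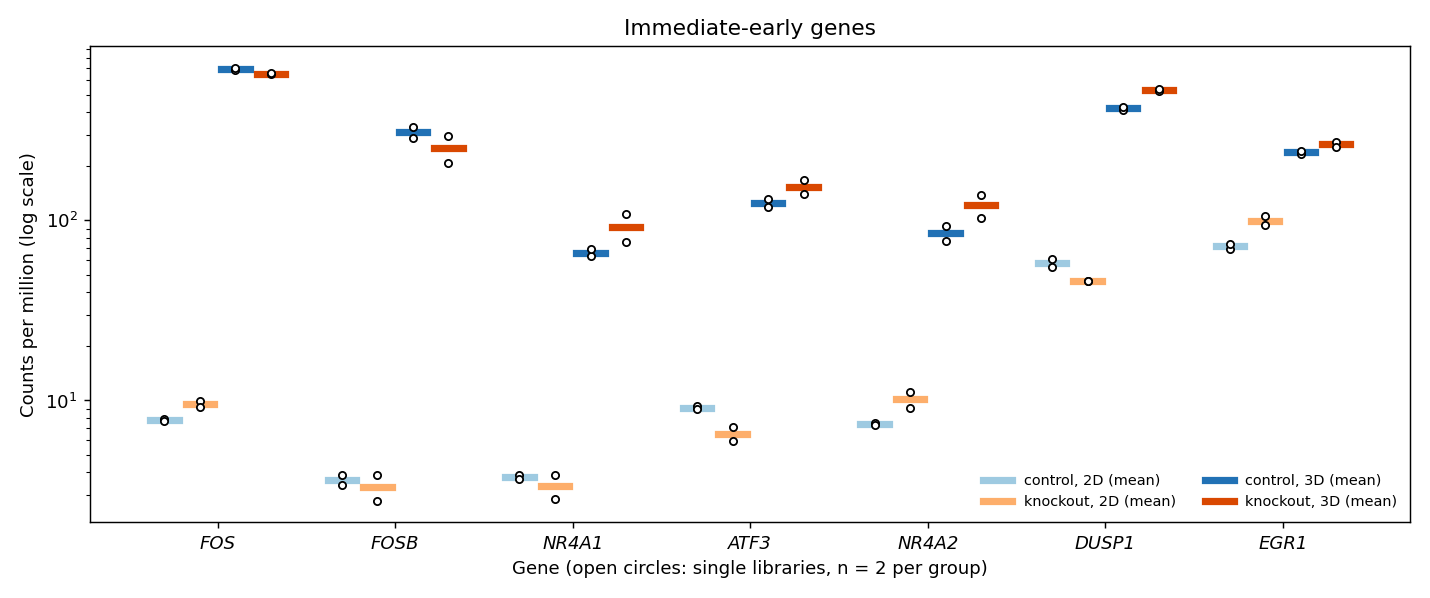
CPM (log scale) of 7 immediate-early genes in the 4 groups, with a line for the group mean and open circles for the 2 libraries. For all 7 genes both gel groups lay above both monolayer groups, with FOS at 697 and 652 CPM in gels against 7.77 and 9.59 CPM in monolayers.

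Of 43 S phase genes, 33 rose (36 adjusted over the list alone), RRM2 from 181 ± 1.03 to 277 ± 3.3 CPM. Their median was 0.29 (adjusted p = 1.11e-13, and adjusted p = 0.0923 with an estimated correlation). Of 38 G2/M genes, 18 rose (20 adjusted over the list alone), such as KIF11 (log2 0.37), against 12 with upper-quartile factors and 8 higher and 1 lower with library size alone. The median was 0.13, or 0.05 with library size alone (adjusted p = 8.34e-05, and adjusted p = 0.293 with an estimated correlation). Of 23 NF-kB targets and cytokines, 16 rose and 2 fell (17 and 2 adjusted over the list alone), with CSF2, a growth factor for myeloid cells, going from 1.08 ± 0.223 to 10.4 ± 0.292 CPM. The median was 0.36 (adjusted p = 7.38e-06, and adjusted p = 0.0923 with an estimated correlation). Of 18 glycolysis genes, 15 rose (15 adjusted over the list alone, with 1 lower), PGK1 by 0.41, against 10 higher and 1 lower with library size alone. The median was 0.32 (adjusted p = 1e-05, and adjusted p = 0.628 with an estimated correlation). Of 25 cholesterol genes, 14 rose and 1 fell (17 and 1 adjusted over the list alone), HMGCS1 by 0.56, against 11 higher and 2 lower with library size alone. Their median was 0.21, or 0.13 with library size alone (adjusted p = 4.79e-05, and adjusted p = 0.489 with an estimated correlation). Of 22 ERK output genes, 15 rose (17 adjusted over the list alone), HBEGF by 0.84 and SPRY2 by 0.77, against 10 higher and 3 lower with library size alone. Their median was 0.21, or 0.13 with library size alone (adjusted p = 0.000101, and adjusted p = 0.489 with an estimated correlation).

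Matrix genes moved both ways in control gels. ADAMTS1, a secreted metalloproteinase, rose from 110 ± 0.0282 to 261 ± 13.7 CPM and CCN2 from 557 ± 7.99 to 916 ± 2.06 CPM, while COL6A3 fell from 37.2 ± 2.56 to 17 ± 0.371 CPM. The largest falls were in TNFSF15, a cytokine of the TNF family, from 44.5 ± 5.69 to 12.8 ± 0.629 CPM, and in CYP24A1, TFEB, PURPL and TMEM161B-DT (log2 -1.30, -1.29, -1.24 and -1.17). Collagens (3 higher and 8 lower of 21, adjusted p = 0.0515), interferon-stimulated genes (2 higher and 7 lower of 37, adjusted p = 0.0515) and hypoxia-response genes (12 higher and 6 lower of 35, adjusted p = 0.601) did not pass as designed. Each of these lists did pass in some alternative with the preset correlation. With scaling by library size alone 6 hypoxia-response genes were higher and 9 lower. Of 16 histone genes, 5 rose (7 adjusted over the list alone). The median was 0.51 (adjusted p = 0.000204, and adjusted p = 0.0976 with an estimated correlation). Of the targets, ETV4 was higher in control gels by 0.19 (adjusted p = 0.0162) and ETV1 by 0.12 (adjusted p = 0.0843). The ETV4 call was lost without control monolayer library 1 (log2 0.10) and without control gel library 1 (0.19) or 2 (0.19), with scaling by library size alone (0.10) and after correction for length and GC content (0.10). Median, mean and camera direction differed in sign for 6 lists without a call: matrix proteases, matrix glycoproteins, the epithelial state, heat shock, mitochondrially encoded genes and endothelial markers.

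In all, 4158 genes changed between control gels and control monolayers, 2486 higher and 1672 lower. The split depended on the scaling: 1239 were higher and 2804 lower with library size alone, 1699 and 2213 with upper-quartile factors, and 2129 and 2148 after correction for transcript length and GC content. The number of changed genes dropped to 2072 without control gel library 1, 2348 without control monolayer library 1 and 2622 without control gel library 2, and 2398 passed by DESeq2. Fold changes followed transcript length here as well, with a rho of -0.23 across genes, against 0.129 with GC content.

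In knockout cells, the same comparison of gels with monolayers asks what collagen culture changed in cells that carried the knockout. Of 35 hypoxia-response genes, 31 fell and 1 rose (33 and 1 adjusted over the list alone), with CA9 going from 19.5 ± 0.899 to 3.61 ± 0.0748 CPM. Their median was -0.51 (adjusted p = 1.8e-12, and adjusted p = 0.335 with an estimated correlation). Of 21 collagens, 13 fell and 3 rose (13 and 3 adjusted over the list alone), with COL6A3 going from 68 ± 2.8 to 18.2 ± 2.05 CPM, COL5A1 from 119 ± 7.37 to 65.3 ± 0.311 CPM. Their median was -0.65 (adjusted p = 0.000564, and adjusted p = 0.335 with an estimated correlation). Of 43 S phase genes, 40 rose (41 adjusted over the list alone). The median was 0.38 (adjusted p = 8.1e-16, and adjusted p = 0.118 with an estimated correlation). Of 38 G2/M genes 32 rose (32 adjusted over the list alone). Their median was 0.29 (adjusted p = 1.52e-11, and adjusted p = 0.153 with an estimated correlation).

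Immediate-early genes rose in knockout gels as well, 20 of 24 (20 adjusted over the list alone, with 1 lower), with FOS going from 9.59 ± 0.53 to 652 ± 4.39 CPM. The median was 0.54 (adjusted p = 3.53e-12, and adjusted p = 0.154 with an estimated correlation). FOSB, NR4A1, ATF3 and NR4A2 changed by 6.23, 4.79, 4.55 and 3.58 on the log2 scale, and the largest falls were in TNFSF15, CST1, TGFBI, CA9 and IL1B (log2 -2.61, -2.61, -2.48, -2.43 and -2.43). Of 30 stress and amino acid genes, 19 rose and 3 fell (19 and 4 adjusted over the list alone), PSAT1 by 0.55. Their median was 0.22 (adjusted p = 9.66e-05, and adjusted p = 0.469 with an estimated correlation). Of 22 ERK output genes, 13 rose and 3 fell (14 and 3 adjusted over the list alone), EREG by 0.75, against 12 and 3 with upper-quartile factors and 11 and 3 with library size alone. The median was 0.17, or 0.11 and 0.10 under these scalings (adjusted p = 0.000985, and adjusted p = 0.409 with an estimated correlation). Of 23 matrix proteases and inhibitors, 13 fell and 4 rose (13 and 5 adjusted over the list alone), PLAT by -0.84 and ADAMTS1 by 1.63. The median was -0.34 (adjusted p = 0.0176, and adjusted p = 0.335 with an estimated correlation). Of 37 interferon-stimulated genes, 14 fell and 4 rose (14 and 4 adjusted over the list alone), STAT2 by -0.60. Their median was -0.23 (adjusted p = 0.0261, and adjusted p = 0.475 with an estimated correlation).

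Of 39 oxidative phosphorylation genes 10 were higher in knockout gels (10 adjusted over the list alone), against 6 with upper-quartile factors and 5 higher and 2 lower with library size alone. The median was 0.09, or 0.04 and 0.02 under these scalings (adjusted p = 0.00356, and adjusted p = 0.475 with an estimated correlation). Of the lists that report RNA quality, ribosomal proteins and histones passed in this comparison, and mitochondrially encoded genes did not. Of 45 ribosomal protein genes, 16 were higher and 1 lower (16 and 1 adjusted over the list alone). Their median was 0.09, or 0.04 with upper-quartile factors and 0.02 with library size alone (adjusted p = 0.00353, and adjusted p = 0.747 with an estimated correlation), with 9 higher and 2 lower under upper-quartile factors and 9 and 4 with library size alone. Of 16 histone genes 5 were higher (4 adjusted over the list alone). The median was 0.55 (adjusted p = 0.00443, and adjusted p = 0.212 with an estimated correlation). Of 13 mitochondrially encoded genes 0 passed by edgeR, DESeq2 or limma-voom, with 0, 2 and 0 at an unadjusted p under 0.05. Their median was -0.43 (adjusted p = 0.0602), and the list passed without knockout gel library 1 (0.00112) and after correction for length and GC content (0.0293), in a range of 0.00112 to 0.566. Median, mean and camera direction differed in sign for 6 lists without a call: the targeted genes, mammary markers, NF-kB targets, SRF and actin genes, heat shock and luminal markers.

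In all, 5915 genes changed between knockout gels and knockout monolayers, 3122 higher and 2793 lower, against 2089 higher and 3539 lower with library size alone and 2293 and 3360 with upper-quartile factors. The calls on matrix proteases and interferon-stimulated genes were lost without knockout monolayer library 2 (adjusted p = 0.0513 and 0.199, ranges 0.0122 to 0.0513 and 0.00199 to 0.199 over the alternatives with the preset correlation). That on ribosomal proteins was lost without knockout gel library 2 (0.0767), with library size alone (0.0704) and after correction for length and GC content (0.179, range 0.000295 to 0.179), and that on oxidative phosphorylation after the same correction (0.172, range 0.000601 to 0.172). Across genes the fold changes had a rho of -0.047 with transcript length and -0.14 with GC content.

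**Figure D4:**
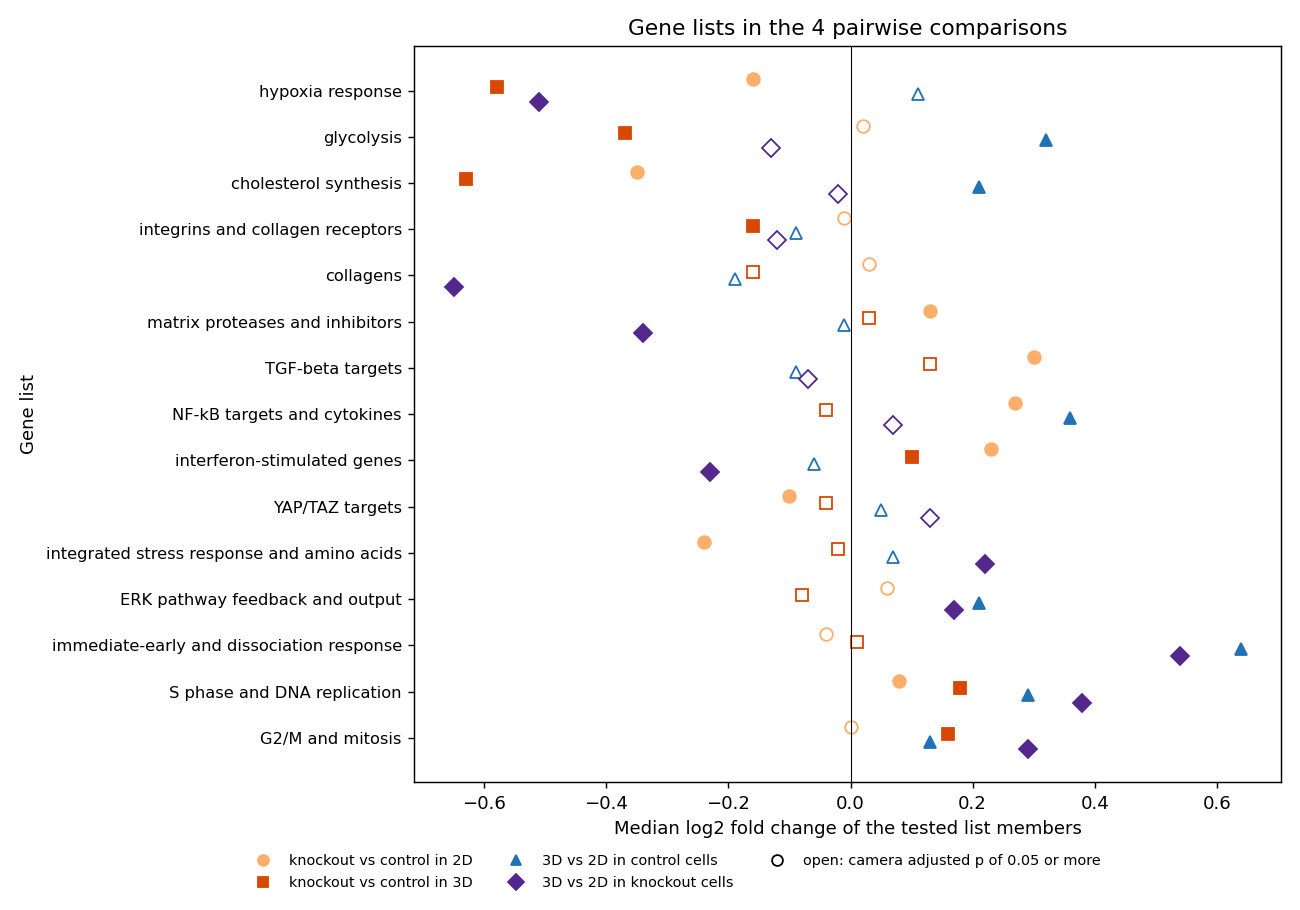
Median log2 fold change of the tested members of 15 gene lists in the 4 pairwise comparisons, filled where camera's adjusted p with the preset correlation was under 0.05 and open otherwise. Hypoxia-response genes had medians of -0.58 and -0.51 in the 2 comparisons that hold the knockout gels against another group, and 0.11 between control gels and control monolayers.

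The interaction asks whether the knockout effect differed between the cultures, which also differed in how the cells were harvested. The interaction, the log2 change in gels minus that in monolayers, was -2.73 ± 0.18 for CA9 (adjusted p = 1.15e-10), -1.09 ± 0.071 for BNIP3 (adjusted p = 9.25e-13) and -1.89 ± 0.13 for CST1 (adjusted p = 4.37e-12). It was negative and past the threshold for 26 of 35 hypoxia-response genes and positive for 1 (31 and 1 adjusted over the list alone). Their median was -0.59 (adjusted p = 1.91e-18, and adjusted p = 0.197 with an estimated correlation). For glycolysis it was negative for 14 of 18 genes (15 negative and 1 positive adjusted over the list alone). Their median was -0.40 (adjusted p = 2.39e-09, and adjusted p = 0.269 with an estimated correlation). For cholesterol synthesis it was negative for 13 of 25 (16 adjusted over the list alone). The median was -0.33 (adjusted p = 4.82e-08, and adjusted p = 0.197 with an estimated correlation). For NF-kB targets and cytokines it was negative for 12 of 23 (12 adjusted over the list alone). The median was -0.44 (adjusted p = 2.39e-09, and adjusted p = 0.111 with an estimated correlation). IL1B stood at 14.9 ± 1.92 CPM in knockout monolayers and at 2.78 ± 0.251 CPM in knockout gels.

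MKI67 was lower in knockout than in control monolayers (440 ± 33.1 and 365 ± 4.56 CPM in control and knockout) and higher in knockout than in control gels, with an interaction of 0.63 ± 0.069 (adjusted p = 7.15e-08), though the difference in monolayers, log2 -0.27, was -0.11 and did not pass after correction for length and GC content. Of 38 G2/M genes the interaction was positive for 7 (14 adjusted over the list alone). Their median was 0.15 (adjusted p = 3.73e-08, and adjusted p = 0.197 with an estimated correlation). The matricellular gene CCN1 was at 1110 ± 13.1 and 764 ± 36.6 CPM in control and knockout monolayers and at 1590 ± 61.3 and 1810 ± 28.7 CPM in control and knockout gels (interaction 0.72 ± 0.065, adjusted p = 1.13e-09). The actin crosslinker gene FLNC had an interaction of 0.70, DUSP1 of 0.67 and ANKRD1 of 0.53. Of 24 YAP/TAZ targets it was positive for 9 and negative for 2 (9 and 3 adjusted over the list alone). Their median was 0.11 (adjusted p = 0.00578, and adjusted p = 0.197 with an estimated correlation). PLAT (-0.91) and PMEPA1 (-1.21) had negative interactions, and the interferon-stimulated genes did not pass as a list (adjusted p = 0.554).

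In all, 1028 genes had an interaction past the threshold, 415 positive and 613 negative, or 581 and 538 after correction for length and GC content. Across 10415 protein-coding genes the interaction had a Spearman rho of -0.333 with GC content and 0.169 with transcript length, and 727 of the 1028 kept their direction and side of the threshold after that correction. The number dropped to 407 without control gel library 1, 613 without control gel library 2, 633 without knockout monolayer library 1, 637 without knockout gel library 2 and 645 without control monolayer library 1, and 628 passed by DESeq2.

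**Figure D5:**
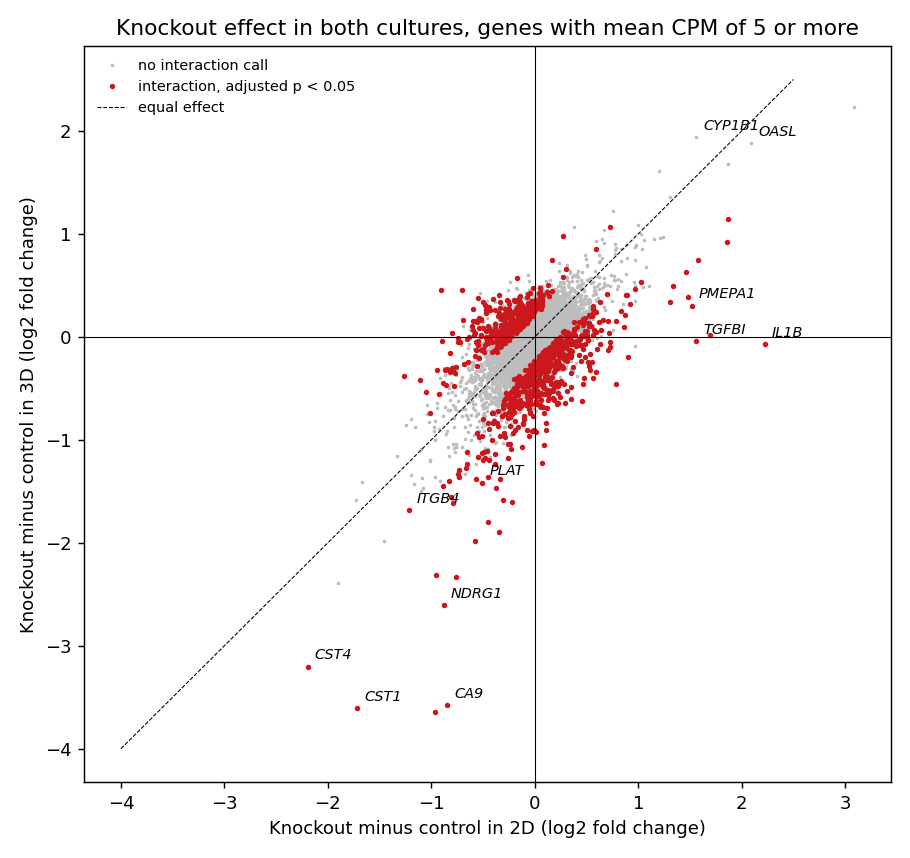
Log2 fold change of knockout against control in monolayers (horizontal axis) and in gels (vertical axis) for each gene with a mean CPM of 5 or more, red where the interaction had an adjusted p under 0.05, with a dashed line of equal effect. CA9, CST1 and NDRG1 lie below the line, and IL1B and TGFBI lie near 0 on the vertical axis.

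Across all tested genes the knockout effect in monolayers and that in gels, which share no library, had a Pearson correlation of 0.456 and a Spearman correlation of 0.409 (genes are not independent replicates, so no p is given). Of 1492 genes called in both cultures, 658 were higher in both, 760 lower in both and 74 opposite, where unrelated lists would share 171.4 and 185.8. For the change from monolayers to gels in control and in knockout cells the correlation was 0.621, and 2770 genes were called in both, 1614 higher in both, 1053 lower in both and 103 opposite.

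The knockout was also set against collagen culture, to ask whether genes changed by the gel in control cells were moved back by the knockout in gels. Changes in the same direction outnumbered those moved back: of 2486 genes higher in control gels, 693 were raised further by the knockout and 337 lowered, and of 1672 genes lower in control gels, 390 were lowered further and 98 raised. Unrelated lists would give 285.2, 309, 207.8 and 191.8. With DESeq2 size factors 415 genes were moved back and 1089 moved in the same direction. The overlap was not run with library size alone or upper-quartile factors. Under these scalings fewer genes were higher than lower in control gels (1239 and 2804, and 1699 and 2213). The gel comparison in control cells and the knockout comparison in gels both use the control gel libraries, which by itself makes opposite changes more likely. In 20 simulations without any effect the fold change correlation was -0.495. On average 0.8 genes were called as opposite there and 0.05 as the same. Almost no gene passes where none differs, so these 2 simulated counts do not size the effect of the shared libraries on the counts in the data. The correlation in the data was -0.00307 (covariance -0.000549, against -0.0215 in the simulations). These are correlations of the fitted fold changes. For differences of mean log2 CPM over all libraries the correlation was 0.0319. In log2 CPM with control gel library 1 in one comparison and library 2 in the other, so that none was shared, it was 0.162 and 0.148. The 435 genes moved back became 186 without control gel library 1, 234 without control monolayer library 1 and 251 without control gel library 2, and the 1083 moved in the same direction became 335, 774 and 387.

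Most leukocyte and fibroblast markers were under 1 CPM, and some markers of other cell types moved with the groups. Of 19 leukocyte markers 15 stayed under 1 CPM in every library, and the highest was LAPTM5 at 53.8 CPM. Of 6 tested, 4 were lower in knockout gels than in knockout monolayers (4 adjusted over the list alone). The median was -0.82 (adjusted p = 0.0176, and adjusted p = 0.335 with an estimated correlation). The call was lost without knockout gel library 1 (0.0627, range 0.0122 to 0.0627 over the alternatives with the preset correlation). Of 6 tested endothelial markers, 4 were lower in knockout than in control gels (4 adjusted over the list alone), ROBO4 from 55.6 ± 1.54 to 21.3 ± 2.52 CPM. The median was -0.37 (adjusted p = 0.0124, and adjusted p = 0.305 with an estimated correlation). The call was lost without control gel library 1 (0.0537, range 0.00393 to 0.0537). Between knockout and control monolayers neither list passed (adjusted p = 0.709 and 0.206), nor did the 11 luminal breast line markers (0.898). Of 14 fibroblast markers, 12 stayed under 1 CPM and COL1A1 was highest, at 18.4 CPM.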

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

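The tests of the patterns below were chosen after the result was seen, except the test of length trends between replicates, which was planned before its result was seen.

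The interaction passed for 1028 genes, which is what set them apart: their knockout effect differed between gels and monolayers. Gels were digested at harvest and monolayers were lysed directly. The interaction therefore also holds any difference of knockout cells in the response to digestion, as does the knockout effect in gels. Of 24 immediate-early and dissociation genes, 4 had a positive and 4 a negative interaction past the threshold. The labels name Cas9 for the control gels and not for the control monolayers. If the latter received none, the knockout effect in monolayers and the interaction also hold an effect of Cas9 that the knockout effect in gels lacks. Across 10415 protein-coding genes the interaction had a rho of -0.333 with GC content and 0.169 with transcript length. After correction for both, 727 of the 1028 genes kept their direction and side of the threshold. Replicates of the knockout groups also differed with GC content, by a rho of -0.485 in monolayers and -0.389 in gels. In the control groups these values were 0.058 and -0.11. Of 230 genes named by the rule in the pairwise comparisons, 92 had an interaction past the threshold.

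Hypoxia-response genes had a median interaction of -0.59, with CA9 at -2.73 and BNIP3 at -1.09. The tables argue against transcript length or GC bias as the whole cause, since the median was still -0.56 after correction, and against a single gel library, since the median knockout effect in gels was at most -0.59 without any 1 of the 4. A different cell number or oxygen supply in the knockout gels stays open: 13 glycolysis genes outside the hypoxia list also had a negative median interaction of -0.31, with 9 of them past the threshold, but neither oxygen nor the cell number at harvest is given. Per the labels all gels were seeded at the same density and volume. The labels give alternative collagen concentrations without saying which gel had which, so the gels may have differed in this. An effect of the 3 factors on the hypoxia program itself may equally give these values.

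Immediate-early genes were higher in gels in control and in knockout cells, with 20 members raised in each. Collagenase digestion and handling at harvest may account for this, since every gel group was digested and no monolayer was, and no digested monolayer, which would separate harvest from culture, is among the 8 libraries. Signalling from collagen culture itself is as open, and the 20 members raised in each gel group cannot tell them apart.

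The knockout effect in monolayers followed transcript length, with a rho of -0.312, medians of 0.08 in genes under 2093 nt and -0.09 in genes over 6615 nt. RNA integrity or fragment length differing between libraries may cause such a trend. Replicates of a group differed with transcript length by a rho of -0.13 at most in size. This lies between the bounds set for and against that cause, which stays open. With GC content, replicates differed by a rho of -0.485 in knockout monolayers and -0.389 in knockout gels, which that test did not cover. The length trend as the whole source of the calls is argued against, since 2387 of 2989 (79.9%) were kept in the same direction after correction for length and GC content. For the calls that were not kept, the trend stays open as a source. An effect of the knockout on genes by their length was not tested.

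The other lists and genes whose knockout effect differed between the cultures are given as values. Glycolysis had a median interaction of -0.40, cholesterol synthesis of -0.33, NF-kB targets and cytokines of -0.44, G2/M and mitosis of 0.15 and YAP/TAZ targets of 0.11, with the tests given above. Collagens, with 6 of 21 members negative and 2 positive past the threshold (13 and 2 adjusted over the list alone), had a median of -0.47 (camera adjusted p = 0.000179, and adjusted p = 0.197 with an estimated correlation). Matrix proteases and inhibitors, with 7 of 23 negative and 1 positive (9 and 1 adjusted over the list alone), had a median of -0.21 (adjusted p = 0.00104, and adjusted p = 0.197 with an estimated correlation). The stress and amino acid list, with 7 of 30 positive (10 positive and 2 negative adjusted over the list alone), had a median of 0.18 (adjusted p = 6.69e-05, and adjusted p = 0.333 with an estimated correlation). S phase and DNA replication, with 2 of 43 positive (3 positive and 1 negative adjusted over the list alone), had a median of 0.09 (adjusted p = 0.000299, and adjusted p = 0.197 with an estimated correlation). Cytoplasmic ribosomal proteins, with 2 of 45 positive and 1 negative (2 and 1 adjusted over the list alone), had a median of 0.08 (adjusted p = 0.000361, and adjusted p = 0.653 with an estimated correlation).

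Integrins and collagen receptors, with 5 of 20 negative (6 adjusted over the list alone), had a median interaction of -0.11, a mean of 0.00 and a downward test (adjusted p = 0.0252, and adjusted p = 0.197 with an estimated correlation), a call lost without knockout monolayer library 2 (0.196), control gel library 1 (0.0587) and knockout gel library 1 (0.0595), in a range of 0.0066 to 0.196. Mitochondrially encoded genes, a sign of RNA quality, with 0 of 13 past the threshold and 0 at an unadjusted p under 0.05 by edgeR, DESeq2 and limma-voom alike, had a median of -0.38 (adjusted p = 0.0258, and adjusted p = 0.658 with an estimated correlation), lost without control monolayer library 1 (0.0559), control gel library 2 (0.418) and knockout gel library 2 (0.307), in a range of 4.27e-05 to 0.418. Leukocyte markers, with 2 of 6 negative (2 adjusted over the list alone), had a median of -0.45 (adjusted p = 0.0275, and adjusted p = 0.269 with an estimated correlation), lost without control gel library 2 (0.151) and knockout gel library 1 (0.0925) and with a prior count of 0.5 (0.0593), in a range of 0.00362 to 0.151. Luminal breast cancer line markers, with 3 of 11 negative (4 adjusted over the list alone), had a median of -0.28 (adjusted p = 0.0252, and adjusted p = 0.306 with an estimated correlation), lost without control monolayer library 1 (0.0933), control gel library 1 (0.0587) and knockout gel library 1 (0.0595) and after the length and GC correction (0.0725), in a range of 0.00771 to 0.0933.

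Among single genes, the interaction was 0.72 for CCN1, 0.70 for FLNC, 0.63 for MKI67, 0.67 for DUSP1 and 0.53 for ANKRD1. It was -1.09 for BNIP3, -1.89 for CST1, -2.73 for CA9, -0.91 for PLAT and -1.21 for PMEPA1.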

How the results depend on the processing

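The length and GC correction was chosen after seeing the data, and the other alternatives were planned. With DESeq2 size factors, upper-quartile factors, library size alone, limma-voom, no filter, the replicate block, only the 2 groups compared and the length and GC correction, each count of changed genes and of lists stayed within 1.5 times the count given, where that alternative was run. After the correction 2387 of 2989, 3389 of 3721, 3443 of 4158, 5333 of 5915 and 727 of 1028 calls kept their direction and side of the threshold in the 5 contrasts, in the order knockout in monolayers, knockout in gels, gels in control cells, gels in knockout cells and interaction. DESeq2's test called 1742, 2352 and 2398 genes in the first 3 contrasts and 628 interactions. Against a fold of 1.5, edgeR called 126, 164, 113, 303 and 19, fewer by construction. With an estimated correlation camera called 0 lists in each of the 5 contrasts, against 4, 6, 5, 4 and 7 of 32 at an unadjusted p under 0.05, and 11, 11, 8, 13 and 15 with the preset one. By fry 14, 21, 10, 21 and 17 lists passed, more than 1.5 times camera's number for knockout in gels and for gels in knockout cells, and the cause was not tested. The correlation of the knockout effects was 0.551 with at least 1 CPM in 4 libraries, where fewer low genes were tested. The ribosomal protein list in control gels against control monolayers had no call as designed (median 0.02, camera adjusted p = 0.991). It passed as lower after the length and GC correction (adjusted p = 0.032, range 0.032 to 0.985), and the cause was not tested.

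Leaving out 1 library at a time leaves fewer samples. It gave 1864 to 2232, 2095 to 3305 and 2072 to 3494 changed genes in the first 3 contrasts, 407 to 1263 interactions, 186 to 430 genes moved back by the knockout in gels, and a correlation of 0.37 to 0.438. Of the tests of named genes without 1 library, 1603 kept their direction and side of the threshold, 80 lost the call and 5 gained it, and of the tests of lists 716, 23 and 29. With 2 libraries per group, 46.2% of simulated interactions of 1.5-fold were recovered with dispersions per gene and 63.1% with trend dispersions.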

Other observations

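The genes below were chosen after their values were seen, and their membership in a family is background. The trefoil genes TFF1, TFF2 and TFF3 and the cystatin genes CST1, CST2, CST3 and CST4, which encode secreted proteins, were lower in knockout cells in both cultures. TFF2 changed by -1.73 in monolayers and -1.58 in gels, TFF3 by -1.35 and -1.77, and TFF1 by -0.98 and -1.26. CST3, cystatin C, changed by -0.24 and -0.67, and the paralogs CST1, CST2 and CST4 by -3.61, -2.60 and -3.20 in gels. Reads of these 3 paralogs may not be fully told apart, which was not tested. Of 4 genes of aldo-keto reductases, which reduce aldehydes and steroids, 3 were higher in both cultures, AKR1B1 at 0.88 and 0.41, AKR1C1 at 1.87 and 1.14 and AKR1C2 at 1.5 and 1.35, while AKR1C3 passed in monolayers alone (0.79, against 0.15 in gels, adjusted p = 0.176). The AKR1C genes are paralogs as well, and how far their reads can be told apart was not tested. TFF1, TFF3, CST2 and AKR1C2 had mean levels of 2.37, 2.73, 1.94 and 3.47 CPM, under the 5 CPM that the naming rule asked for. Of 7 genes known as targets of the aryl hydrocarbon receptor or of NRF2, 5 passed as higher in both cultures, CYP1B1 at 1.56 and 1.94, TIPARP at 0.44 and 0.41, NQO1 at 0.36 and 0.58, GCLM at 0.47 and 0.52 and GCLC at 0.31 and 0.41. TXNRD1 did not pass (adjusted p = 0.154 and 0.108), and CYP1A1 passed in gels (0.98) but not in monolayers (adjusted p = 0.194). Of genes of the BMP pathway, the ligand gene BMP4 was at 0.58 and 0.64. Among the others, ID3 was at 0.75 and 1.22, ID4 at 0.41 and 0.61 and SMAD7 at 0.67 and 0.57. ID1 passed in gels (0.75) but not in monolayers (adjusted p = 0.121), and SMAD6 and SMAD9 did not pass.

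In gels against monolayers, the metallothionein genes MT1E, MT1X and MT2A, whose products bind zinc, were higher in control and knockout cells. MT1E went from 19.9 to 73.4 CPM in control cells (log2 1.88, and 2.05 in knockout cells), MT2A from 297 to 543 CPM (0.87 and 0.83), and MT1X changed by 1.15 and 1.34, beside the zinc exporter SLC30A1 (1.63 and 1.13). Glucocorticoid-induced SGK1 (2.13 and 2.14) and TSC22D3 (1.37 and 1.69) were also higher, FKBP5 passed in knockout cells (0.63) but not in control cells (adjusted p = 0.0678), and PER1 did not pass. Within the knockout groups, the replicate difference followed GC content across genes, with a rho of -0.485 in monolayers and -0.389 in gels, against 0.058 and -0.11 in the control groups.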
